A study of Drosophila melanogaster with 6 samples.

How the data were processed

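Gene expression was measured in whole ovaries of Drosophila melanogaster with single-colour Affymetrix 3-prime arrays, 1 array for each of 6 samples. Per the labels' protocols, each sample held the ovaries of 50 females aged for 36 hours at 25 degrees C with wet yeast, and biotin-labelled RNA was made from 100 ng of total RNA. The labels put 3 samples in the wild type group and 3 in the ttk^twk homozygous group and number them as biological replicates 1 to 3 in each.

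The values used are the authors' deposited log2 expression values, 1 column per array and 1 row per probe set. The submitters' processing notes name GCOS, MAS5, Affymetrix Expression Console and RMA, with no role, order or version for any of them. The deposited values run from about 3 to 15 on each array with near-identical quartiles, a range of log2 RMA values rather than of linear MAS5 signals. The scale was therefore read as log2 from the values. The background step, the normalization and any centring beyond that are not given in the sources used here. The direction of each difference was set here as ttk^twk minus wild type. Scanner files were not used here, and no detection call stood beside a value.

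The table held 18952 probe sets. The 183 control probe sets were left out of the tests, which left 18769. The platform annotation given for the probe sets listed 1 gene symbol for 13647 of them, several genes for 402 and none for 4720. Of the probe sets with 1 symbol, 13544 were found through their Entrez gene number in the RefSeq gene table of assembly Release 6 plus ISO1 MT, and 0 symbols changed. That table was used only for names and chromosome arms, since no genome build is named for the arrays. Probe sets with several genes or none entered the tests but were not named. A gene with several probe sets was represented by the one with the highest mean over the 6 arrays, which gave 11982 genes.

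Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 4 residual degrees of freedom, 4.69 prior degrees of freedom) on the deposited log2 values, and p-values were adjusted with the Benjamini-Hochberg method over the 18769 probe sets. A probe set was called at an adjusted p under 0.05. Gene lists were tested with camera at a preset correlation of 0.01 on 1 probe set per gene, adjusted over 32 lists, and again with an estimated correlation and with fry. Camera compares a list with all other genes. The directional test of fry asks whether the genes of a list move on balance one way, and its mixed test whether they change in either direction, and neither compares the list with other genes. For each list, members were counted as called over all probe sets and as called when adjusted over the list alone. Intervals of list medians are 95% bootstrap intervals over 2000 resamples of genes. Called shares by chromosome arm were compared with Fisher's exact test, two-sided. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

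The tests, the gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule takes ry and ttk, the 3 genes that the published study of this mutant follows, the 12 highest and 12 lowest log2 changes among called genes whose groups do not overlap, and from each list up to 4 called members with the largest changes, or, where none was called, the 2 with the smallest p. Other genes named below were chosen after their values were seen: all chorion genes, the 2 laminin and collagen examples, the muscle examples, the chromosome 4 genes and the genes with disagreeing probe sets. No probe set was paired with ttk in the annotation used, so the mutated gene is not analysed here and the genotype labels have no check at that gene. The same holds for other list members that the annotation did not pair with a probe set. Measured were 14 of 23 fixed members for Notch, 19 of 27 for EGFR signalling and 32 of 38 for endocytosis. For actomyosin it was 25 of 41, for ribosome 18 of 53 and for heat shock 11 of 21. Each list result covers the measured members only.

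The same replicate numbers stand in both groups, so deviations from the group means were correlated between groups over the 7021 probe sets with a mean above 7. Samples with the same number correlated at 0.297, 0.286 and 0.162, and samples with different numbers at -0.341 to 0.0677. The numbers were therefore taken to pair the samples. This pairing comes from the data alone, since the labels do not say what samples of 1 number share. The main model has no block, as fixed beforehand, and a model with the replicate block was run as an alternative.

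Alternatives were quantile normalization, centring on the median or on the 75th percentile, removal of the dimmest 40% of probe sets, 1 probe set per gene, averaged probe sets, eBayes with trend and robust options, array weights, the replicate block, a pseudocount of 16 on the linear scale and each array left out in turn. Leaving out wild-type replicates 1 and 2 together was added after the data were seen.

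The code was tested on simulated data for the comparison of ttk^twk with wild type over 18769 probe sets, with 50 probe sets changed at each of 4 sizes. It called 25 of 50 at a log2 change of 0.5, 48 of 50 at 1, 50 of 50 at 2 and 50 of 50 at 3, each with the right sign, and 5 of its 178 calls were false. The changed probe sets were drawn only from those brighter than the array medians, and the noise was independent between probe sets and between arrays. These rates therefore do not cover dim probe sets or effects that arrays share. The number of arrays limits the precision. An exact permutation test of 3 against 3 arrays cannot give a two-sided p below 0.1, so single values were tested only through limma.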

Results

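The ttk^twk allele, named twin peaks, affects tramtrack, which encodes zinc finger transcription factors. The dorsal appendages of the Drosophila eggshell are shaped by tubes of follicle cells, and per the labels the expansion of these tubes is defective in ttk^twk egg chambers. The comparison asks which transcripts differ in level between whole ovaries of wild-type females (3 arrays) and of ttk^twk homozygous females (3 arrays), dissected at 36 hours after eclosion, an age chosen to hold many egg chambers in tube expansion. The labels give the Canton S background for both genotypes and add rosy to the mutant genotype. A whole ovary also holds germline cells, younger egg chambers and a muscular sheath, so each value is a mean over all of these. The median deposited log2 value over the 18769 probe sets tested was 5.41, 5.39 and 5.45 for wild-type replicates 1, 2 and 3 and 5.41, 5.39 and 5.42 for mutant replicates 1, 2 and 3.

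Among the largest changes were those of Rab40, Cyp9b2, Elovl7 and Cyp12d1-d. Rab40, a small GTPase gene of the Rab family, rose 39.6-fold in the mutant, and the cytochrome P450 gene Cyp9b2 rose 26.0-fold. The fatty acid elongase gene Elovl7 and the cytochrome P450 gene Cyp12d1-d were 39.5-fold and 34.8-fold lower in the mutant. Rab40 in wild type and Elovl7 and Cyp12d1-d in the mutant have means below the array median, where no detection call separates signal from background, so these 3 folds are best read as lower bounds and not ranked. The same holds below for every gene whose lower mean lies under the array median, among them CG18628, CG15601, CG17684, nrv3, CG43064, pigs and lncRNA:CR32368. In all, 1652 of 18769 probe sets were called at an adjusted p under 0.05 (limma), 837 higher and 815 lower in the mutant, and 296 of these changed at least 2-fold, 142 higher and 154 lower. The balance of directions depends on the scaling, with 871 higher and 736 lower after centring on the median and 706 higher and 928 lower after centring on the 75th percentile. By the brightest probe set of each gene, 1285 of 11982 genes were called, 675 higher and 610 lower. The count fell to 1066 without mutant replicate 1 and to 1007 without mutant replicate 2, and it was 1068 without wild-type replicates 1 and 2.

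Among the 12 genes listed for large rises, Rab40 went from a log2 value of 4.75 ± 0.77 (SD, n = 3) in wild type to 10.06 ± 0.03 in the mutant, a log2 change of 5.31 ± 0.31 (SE, adjusted p = 1.1e-05). Cyp9b2 went from 6.16 ± 0.20 to 10.86 ± 0.25 (adjusted p = 2.3e-07), and the peroxiredoxin gene Prx6c from 5.54 ± 0.15 to 9.12 ± 0.28 (adjusted p = 1.2e-06). nrv3, which encodes a beta subunit of the sodium pump, rose by a log2 change of 3.24 ± 0.18 (SE). The other rises of this size were in genes known mostly by number. They were CG18628 at 4.47, CG12560 at 3.82, CG15601 at 3.55, CG9380 at 3.48, CG18598 at 3.36, CG17684 at 3.30, CG7997 at 3.19 and the non-coding gene CR43790 at 3.09 on the log2 scale. For CG17684 the other probe sets, both dim, gave 0.05 and 0.12 and were not called, so its probe sets disagree. A dimmer probe set of CG9380 rose by less, 1.04 (adjusted p = 3.3e-05).

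Among the 12 genes listed for large losses, Elovl7 went from 10.42 ± 0.18 (SD, n = 3) to 5.12 ± 1.05, a log2 change of -5.31 ± 0.42 (SE, adjusted p = 7.5e-05). Cyp12d1-d changed by -5.12 ± 0.28 (SE) and the carbonic anhydrase gene CAH2 by -3.40 ± 0.19. pigs, a gene of the Gas2 family that links cytoskeletal filaments, changed by -3.40 ± 0.19 as well. The neighbouring gene numbers CG15570 and CG15571 fell by 3.07 and 3.96 on the log2 scale. CG31926, CG43064, CG14879 and CG8768 changed by -4.42, -4.22, -3.74 and -3.26, CG12716 went from 10.10 to 7.10, and the non-coding gene lncRNA:CR32368 by -2.98. With eBayes trend and robust options the adjusted p was 0.0697 for CG15571 and 0.0512 for lncRNA:CR32368, the highest of their 17 alternatives, whose lowest were 4.2e-05 and 4.0e-06. Elovl7 stood at 6.33 in mutant replicate 3, against 4.48 and 4.54 in mutant replicates 1 and 2.

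**Figure D1:**
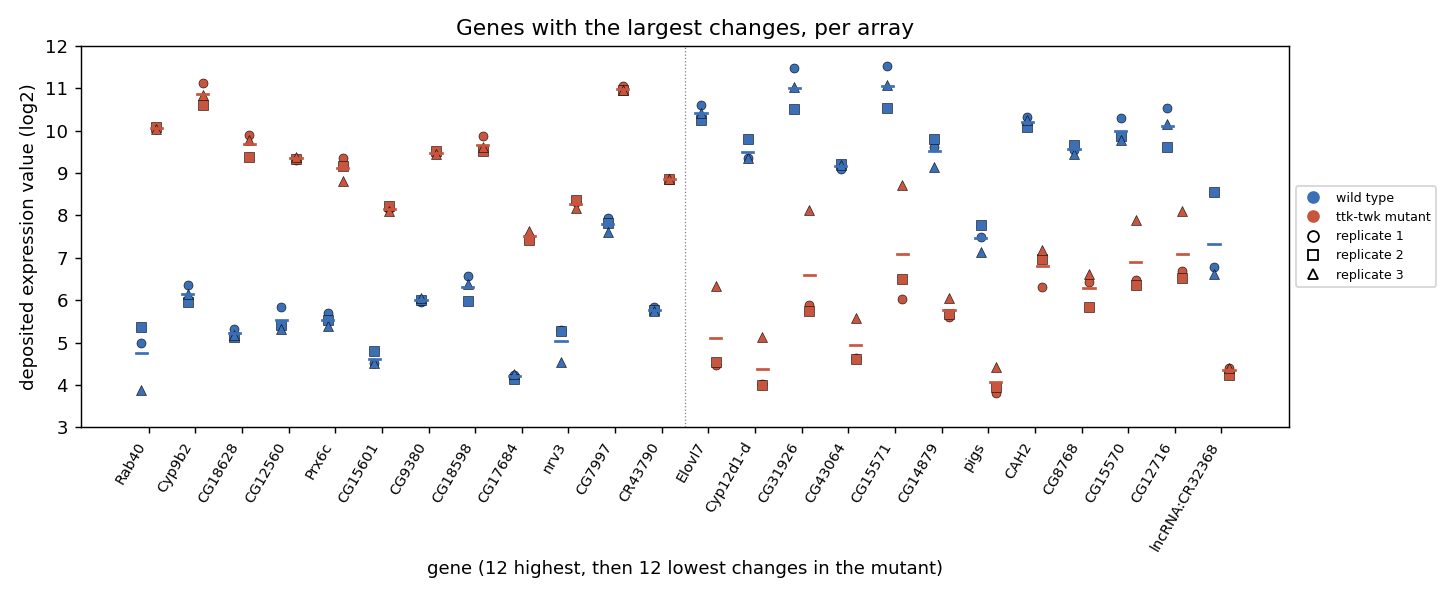
Deposited log2 value (vertical axis) of 12 genes with large rises and 12 with large losses in the mutant (horizontal axis), 1 point per array, blue for wild type and red for ttk^twk, with a bar at each group's mean. The genes were chosen among those whose genotypes do not overlap, so the lack of overlap is no result. Mutant replicate 3 (red triangles) lies at 8.71 for CG15571 against 6.03 and 6.51 for the other mutant arrays.

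The genes that the published study of this mutant follows in tube expansion were all lower in the mutant. Pax, which encodes the focal adhesion adaptor Paxillin, fell 2.32-fold, from 9.44 ± 0.07 to 8.23 ± 0.16 (SD, n = 3), a log2 change of -1.21 ± 0.09 (SE, adjusted p = 3.8e-05). The transcription factor gene mirr changed by -0.44 ± 0.10 on its brightest probe set (adjusted p = 0.0245) and by -1.06 ± 0.06 on a dimmer one (adjusted p = 8.2e-06). shi, which encodes Dynamin, changed by -0.28 ± 0.07 (adjusted p = 0.0407), and its other probe sets gave -0.73 (adjusted p = 0.00051) and 0.01 (adjusted p = 0.950). All 3 were called over all probe sets and adjusted over the list alone, which is not independent evidence, since the study chose them on these samples. The list fell as a set (camera adjusted p = 0.0040), with adjusted p = 0.755 with an estimated correlation and 0.0095 with fry, and 0.0877 without wild-type replicates 1 and 2, in a range of 0.00034 to 0.755 over its alternatives. On the brightest probe sets, shi passed only without wild-type replicate 2 (adjusted p = 0.0363) and mirr only without wild-type replicate 3 (adjusted p = 0.0021) among the fits that leave out 1 array, and otherwise reached 0.157 and 0.0977. With the replicate block the adjusted p of shi was 0.0512, in a range of 0.0055 to 0.166 over its alternatives, and that of mirr ranged from 0.00017 to 0.243.

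ry, the xanthine dehydrogenase gene that the mutant genotype label names as rosy, was not lower in the mutant. It rose from 4.86 ± 0.07 to 5.56 ± 0.17 (SD, n = 3), a log2 change of 0.70 ± 0.09 (SE, adjusted p = 0.0016). Its mean lies at the 46.2 percentile of all probe sets, so it is dim on both sides. The labels do not say which part of ry the allele affects, so the probe set checks no label.

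Eggshell genes changed in part. Of 7 measured chorion genes of the X and 3L clusters, which build the outer eggshell, 3 fell: Cp16 by a log2 change of -1.93 ± 0.29 (SE, adjusted p = 0.0036), Cp19 by -1.81 ± 0.27 (adjusted p = 0.0033) and Cp18 by -1.40 ± 0.21 (adjusted p = 0.0033). Cp15 (-0.11), Cp36 (0.02), Cp38 (0.02) and Cp7Fc (0.56) were not called. Adjusted over the list alone, 3 fell and Cp7Fc rose. Cp15, Cp36 and Cp38 lie within 0.5 of the highest value of the table, 14.88, where a change would be hard to see. The wild-type means of Cp16 (14.40) and Cp19 (14.56) lie within the same margin, so 5 of 7 genes are near the ceiling in wild type and the changes of Cp16 and Cp19 are best read as lower bounds. Cp16, Cp18, Cp19 and Cp15 are on arm 3L and Cp36, Cp38 and Cp7Fc on X. Mutant replicate 3 was nearest to wild type for Cp16, at 13.25 against 12.30 and 11.86. With eBayes trend and robust options the 3 calls were lost (adjusted p = 0.0684 for Cp16, 0.0652 for Cp19 and 0.0556 for Cp18), the highest of their alternatives, whose lowest were 9.0e-05, 0.00035 and 0.00024. Without wild-type replicates 1 and 2 the adjusted p was 0.0531 for Cp19 and 0.0504 for Cp18. The list as a set did not pass (camera adjusted p = 0.134), except without mutant replicate 3 (adjusted p = 0.0213), in a range of 0.0213 to 0.984 over its alternatives.

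**Figure D2:**
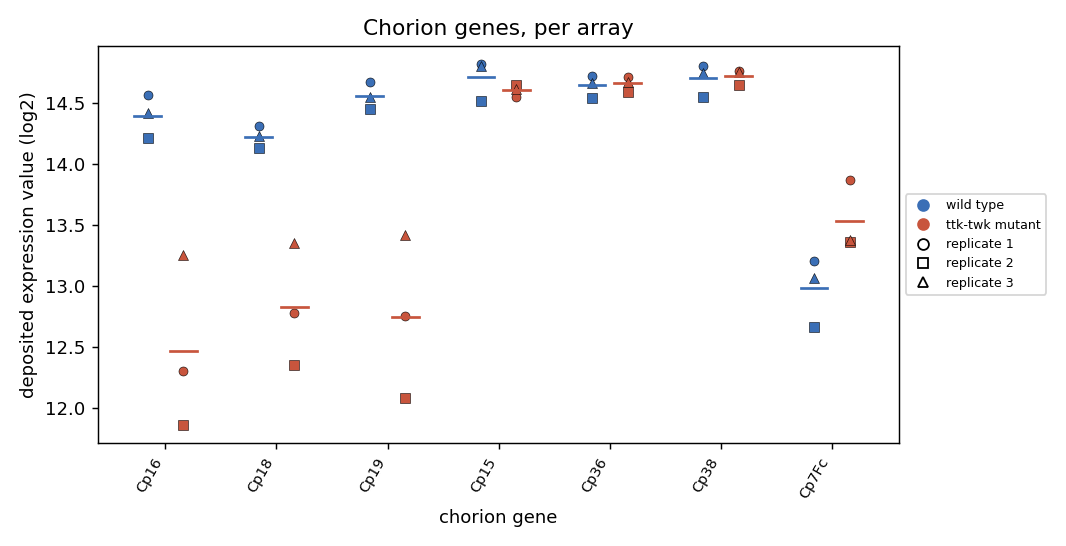
Deposited log2 value (vertical axis) of the 7 measured chorion genes (horizontal axis), 1 point per array, blue for wild type and red for ttk^twk, with a bar at each group's mean. Cp16, Cp18 and Cp19 separate the genotypes, while Cp15, Cp36 and Cp38 lie between 14.52 and 14.82 on all 6 arrays.

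Among 16 genes listed for the vitelline membrane, the inner eggshell layer, Muc4B (-1.02 ± 0.17, SE, adjusted p = 0.0059) and Vm26Ac (-0.68 ± 0.11, adjusted p = 0.0044) fell and 1 gene rose, with 3 higher and 3 lower adjusted over the list alone. Not every gene of this list encodes a part of that layer. The set did not pass (camera adjusted p = 0.869). Its median change was 0.02 and its mean -0.06, and camera's direction was down. Of the 4 yolk genes, 0 were called by limma, 2 had an unadjusted p under 0.05 and 2 were lower adjusted over the list alone. Yp3 (-0.22) and Yp2 (-0.17) had the smallest p, and the set did not pass (camera adjusted p = 0.0866). It passed in 2 of 19 alternatives, in a range of 0.0194 to 0.984.

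Among the signalling lists, ecdysone genes held the most calls. Of 23 ecdysone genes, 2 rose and 4 fell, over all probe sets and adjusted over the list alone. Cyp18a1, which inactivates ecdysone, had a log2 change of -1.72 ± 0.09 (SE, adjusted p = 6.5e-06), and its other probe set gave -1.56. spo, which acts early in ecdysone synthesis, rose by 1.14 ± 0.13 (adjusted p = 0.00064), and nvd, which acts at the first step, changed by -0.77 ± 0.11 (adjusted p = 0.0023). MsrA, a methionine sulfoxide reductase gene induced by ecdysone, rose by 1.24 ± 0.10 (adjusted p = 7.8e-05). Of 10 genes of the JNK and AP-1 pathway, 2 rose, over all probe sets and adjusted over the list alone. Gadd45, a stress response gene, had the larger change, 1.07 ± 0.15 (adjusted p = 0.0019). Of 19 genes of EGFR signalling 2 were lower (3 adjusted over the list alone), and of 17 genes of BMP signalling 3 were lower (4 adjusted over the list alone). None of these calls held in all 6 fits that leave out 1 array, where the highest adjusted p was 0.0977 for mirr (without mutant replicate 3), 0.0904 for grk (without mutant replicate 1), 0.133 for dpp (without wild-type replicate 1), 0.108 for daw (without mutant replicate 3) and 0.0649 for tkv (without mutant replicate 2). The Notch list lacks N, Dl, Ser and Su(H), which were not paired with a probe set. Of its 14 measured genes limma called 0 (0 adjusted over the list alone, 3 at an unadjusted p under 0.05), by the brightest probe sets, and ct (-0.34) and E(spl)m3-HLH (-0.42) had the smallest p. A dimmer ct probe set was called at -0.50 (adjusted p = 0.0150) and another gave -0.06. Of 11 JAK-STAT genes it called 0 (1 higher adjusted over the list alone, 2 at an unadjusted p under 0.05), with Ptp61F at 0.28 and dome at 0.15, while a dimmer Ptp61F probe set was called at 0.47 (adjusted p = 0.0128). None of these 6 lists passed camera, with adjusted p = 0.574 for ecdysone, 0.134 for JNK, 0.574 for EGFR, 0.360 for BMP, 0.645 for Notch and 0.869 for JAK-STAT.

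Some adhesion, junction and trafficking genes changed, in both directions, and most were not called. Of 23 integrin and focal adhesion genes, 2 rose and 4 fell (2 and 5 adjusted over the list alone). Pax had the largest change, and Itgbn, a beta integrin gene, rose by 0.75 ± 0.08 (SE, adjusted p = 0.00058). The list did not pass (camera adjusted p = 0.0716, 0.0217 with the replicate block, 0.984 with an estimated correlation). The fits without wild-type replicate 3 (adjusted p = 0.0056) or mutant replicate 2 (0.0312) did, as did quantile normalization (0.0304) and array weights (0.0490), 5 of 19 alternatives with the block, in a range of 0.0056 to 0.984. Of 32 endocytosis genes, 4 rose and 4 fell (5 and 4 adjusted over the list alone). Vps25, a component of the ESCRT machinery, rose by 0.84 ± 0.07 (adjusted p = 9.3e-05) and nwk, which encodes an F-BAR protein, changed by -0.55 ± 0.08 (adjusted p = 0.0022), while a dimmer nwk probe set gave -0.05. Of 23 genes of the septate junction list, 3 rose and 4 fell (5 and 4 adjusted over the list alone). Ssk, a smooth septate junction gene, rose by 0.72 ± 0.10 (adjusted p = 0.0023), and Tret1-1, a trehalose transporter gene, changed by -0.62 ± 0.08 (adjusted p = 0.00098). Of 23 adherens junction and polarity genes, 3 rose and 2 fell (3 and 4 adjusted over the list alone), where the call of Nrg (-0.32) is lost with the replicate block (adjusted p = 0.0594, range 0.0026 to 0.303 over its alternatives). Dimmer Nrg probe sets were called in the main fit at -0.59 (adjusted p = 0.0016) and -0.46 (adjusted p = 0.0128). Of 25 actomyosin genes 1 fell, over all probe sets and adjusted over the list alone. Camera gave adjusted p = 0.946 for endocytosis, septate junctions and adherens junctions and 0.574 for actomyosin. The adherens list had a median of -0.0095 and a mean of 0.01, and the septate list -0.03 and 0.01, with camera's direction down for both.

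Basement membrane genes were lower in the mutant as a set. Of 18 measured members, 6 fell and 1 rose (10 and 1 adjusted over the list alone), and the median log2 change was -0.40 (95% bootstrap interval -0.50 to -0.10, camera adjusted p = 0.0012, adjusted p = 0.984 with an estimated correlation, 0.203 with fry). AdamTS-A, a secreted metalloprotease gene, changed by -0.75 ± 0.11 (SE, adjusted p = 0.0024), while its dimmer probe set gave -0.15, and PH4alphaEFB, a prolyl hydroxylase gene that modifies collagen, changed by -0.65 ± 0.10 (adjusted p = 0.0038). The laminin gene LanA (-0.41) and the collagen gene Col4a1 (-0.40) were not called. Muscle markers moved with this list. Their median log2 change was -0.24 (95% bootstrap interval -0.42 to -0.13, camera adjusted p = 0.0041, adjusted p = 0.984 with an estimated correlation, 0.298 with fry), -0.12 without wild-type replicate 2 and -0.37 without wild-type replicate 3, and of 22 measured, 1 rose and 2 fell (1 and 4 adjusted over the list alone). The troponin C genes TpnC4 (-1.35 ± 0.06) and TpnC41C (0.86 ± 0.07) changed in opposite directions. Both are dim, with means at the 32.8 and 28.7 percentile of all probe sets. The brighter TpnC73F changed by -0.79 ± 0.18 (adjusted p = 0.0264), from 8.72 in wild type to 7.93 in the mutant. It was called in 2 of the 6 fits that leave out 1 array, and its dimmer probe set gave -0.05. The median deviation of the muscle markers from their mean over the 6 arrays was 0.24, 0.33 and -0.24 in wild-type replicates 1, 2 and 3 and -0.09, -0.16 and -0.12 in mutant replicates 1, 2 and 3. That of the basement membrane genes was 0.26, 0.36 and -0.08 in wild type and -0.15, -0.19 and -0.25 in the mutant. The muscle list did not pass without wild-type replicate 1 (adjusted p = 0.0538) or 2 (0.106). Without both, the camera adjusted p was 0.375 for the basement membrane list (median -0.13) and 0.751 for the muscle list (median 0.095), in ranges of 2.9e-08 to 0.984 and 3.0e-09 to 0.984 over their alternatives.

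DNA replication and cell cycle genes were slightly higher in the mutant as sets, mainly against wild-type replicates 1 and 2. Of 26 genes of DNA replication and chorion gene amplification, 2 rose and 0 fell, over all probe sets and adjusted over the list alone, and 23 had a positive change (median 0.16, camera adjusted p = 0.0041, adjusted p = 0.984 with an estimated correlation, 0.152 with fry). Orc4, a subunit of the origin recognition complex, rose by 0.61 ± 0.06 (SE, adjusted p = 0.00041). Of 19 mitotic cell cycle genes, limma called 0 (0 adjusted over the list alone, 7 at an unadjusted p under 0.05), and the median change was 0.14 (camera adjusted p = 0.0087, adjusted p = 0.984 with an estimated correlation, 0.203 with fry). The smallest p belonged to twe (0.42, adjusted p = 0.0574, 0.0099 with the replicate block, range 0.0099 to 0.181 over its alternatives) and sub (0.25, adjusted p = 0.0628). The cell cycle list did not pass without wild-type replicate 2 (adjusted p = 0.0740). Wild-type replicates 1 and 2 lay at -0.10 and -0.13 for DNA replication and at -0.11 and -0.15 for the cell cycle, opposite in sign to the muscle markers at 0.24 and 0.33, and wild-type replicate 3 lay at 0.02, 0.03 and -0.24. Without wild-type replicates 1 and 2 the median change was 0.05 for DNA replication and 0.04 for the cell cycle. Over their alternatives the camera adjusted p ranged from 0.00017 to 0.984 and from 0.00036 to 0.984. Tissue carried in wild-type replicates 1 and 2 and the genotype cannot be told apart for these sets.

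**Figure D3:**
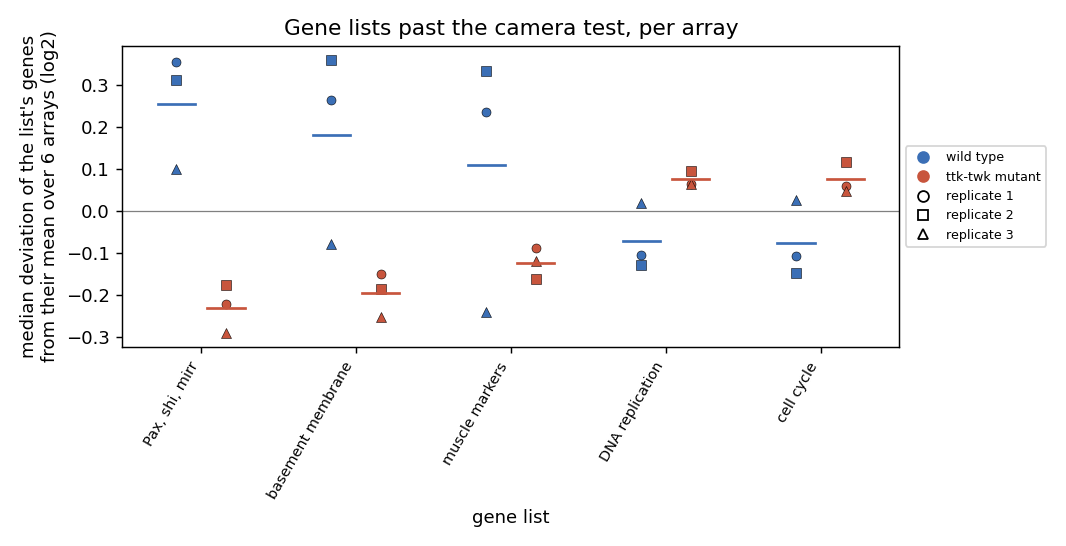
Median deviation (vertical axis, log2) of the genes of 5 lists (horizontal axis) from their own mean over the 6 arrays, 1 point per array, blue for wild type and red for ttk^twk, with a bar at each group's mean. For the muscle markers wild-type replicate 3 lies at -0.24, below the mutant arrays, while wild-type replicates 1 and 2 lie at 0.24 and 0.33.

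Germline genes showed no shift as a set. Of 33 measured, 3 rose and 2 fell (3 and 4 adjusted over the list alone, camera adjusted p = 0.819). bam, which drives the differentiation of germline stem cell daughters, rose by 0.69 ± 0.09 (SE, adjusted p = 0.0017), and AGO3, an Argonaute of the piRNA pathway, by 0.63 ± 0.10 (adjusted p = 0.0039). Of 25 piRNA pathway genes, 2 rose and 1 fell, over all probe sets and adjusted over the list alone (camera adjusted p = 0.645), and SoYb, a Tudor domain gene, rose by 0.68 ± 0.08 (adjusted p = 0.00072). The lower one is papi (-0.33, adjusted p = 0.0382), which is not called with the replicate block (0.0634) and is called only without wild-type replicate 3 (0.0329) among the 6 fits that leave out 1 array, with 0.157 without mutant replicate 2 and a range of 0.0132 to 0.185 over its alternatives.

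Some detoxification genes changed strongly, in both directions. Of 27 measured, 4 rose and 4 fell (6 and 4 adjusted over the list alone, camera adjusted p = 0.946). Besides Cyp9b2, the glutathione transferase gene GstE1 fell 7.50-fold (-2.91 ± 0.10, SE, adjusted p = 4.9e-07), GstD2 fell 2.23-fold (-1.16 ± 0.08, adjusted p = 3.0e-05) and the juvenile hormone epoxide hydrolase gene Jheh2 fell 2.14-fold (-1.10 ± 0.08, adjusted p = 5.4e-05). The list's median and mean, 0.03 and 0.02, were above 0 while camera's direction was down. Of 28 cuticle and chitin genes, 0 rose and 3 fell (3 and 6 adjusted over the list alone, camera adjusted p = 0.645). The imaginal disc growth factor gene Idgf3 changed by -0.97 ± 0.09 (adjusted p = 0.00018) and obst-B, a chitin binding gene, by -0.56 ± 0.08 (adjusted p = 0.0020), and a dimmer Idgf3 probe set gave -0.21.

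Housekeeping, stress and immune lists did not pass in the main test. Of 18 ribosomal protein genes, 1 rose, over all probe sets and adjusted over the list alone (RpL27, 0.41 ± 0.06, SE, adjusted p = 0.0037), and camera gave adjusted p = 0.956, with a median of -0.0053, a mean of 0.01 and the direction down. Of 26 mitochondrial respiration genes limma called 0 (0 adjusted over the list alone, 2 at an unadjusted p under 0.05, camera adjusted p = 0.0716), with ATPsynC at -0.18 and ox at -0.21. The respiration list passed without wild-type replicate 3 (adjusted p = 0.0065) and without mutant replicate 3 (0.0269), and with quantile normalization (0.0304), centring on the 75th percentile (0.0410), eBayes trend and robust options (0.0194) and the pseudocount (0.0304), 6 of 19 alternatives in a range of 0.0065 to 0.984. Of 11 heat shock genes it called 0 (0 adjusted over the list alone, 3 at an unadjusted p under 0.05, camera adjusted p = 0.855), and stv (-0.38) had an adjusted p of 0.0992, 0.0436 with the replicate block, in a range of 0.0059 to 0.636. Of 20 immune genes 1 rose, over all probe sets and adjusted over the list alone (camera adjusted p = 0.855). It was PGRP-LB, an amidase gene that degrades peptidoglycan, at 0.77 ± 0.14 (adjusted p = 0.0098). The immune list's median was 0.02 and its mean -0.0040, with the direction up.

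Markers of other tissues that a dissected ovary could carry, apart from muscle, did not shift as sets, but many of them are dim. A mean above 7 was reached by 1 of 13 gut, 1 of 12 spermatheca and oviduct and 1 of 12 neuron markers. It was reached by 4 of 7 fat body and 4 of 13 hemocyte markers. Dim members could hardly show a fall. Of 7 fat body markers 1 rose and 1 fell, over all probe sets and adjusted over the list alone (camera adjusted p = 0.855), and the lower one, Obp99b (-0.42), is not called with the replicate block (adjusted p = 0.0510, range 0.0072 to 0.179 over its alternatives). Of 13 hemocyte markers 2 rose and 0 fell (2 and 2 adjusted over the list alone, camera adjusted p = 0.946), among them NimC1, a phagocytic receptor gene, at 0.44 ± 0.06 (SE, adjusted p = 0.0016). Limma called 0 of 13 gut markers (2 at an unadjusted p under 0.05), 0 of 12 spermatheca and oviduct markers (0 at an unadjusted p under 0.05) and 0 of 12 neuron markers (3 at an unadjusted p under 0.05), with 0 adjusted over each list alone. Camera gave adjusted p = 0.946, 0.946 and 0.266 for these lists, and the gut list had a median of -0.01 and a mean of 0.01 with the direction up. The neuron gene elav (-0.45) had an adjusted p of 0.140, 0.0423 with the replicate block, in a range of 0.0016 to 0.907.

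Genes of the chromosome arm that carries ttk were not called more often than others. On 3R, where ttk and ry lie, 285 of 2972 genes were called (9.59%), against 256 of 2203 on 2L, 284 of 2426 on 2R, 246 of 2344 on 3L and 191 of 1869 on X. The odds ratio of a call on 3R against the other major arms was 0.85 (95% interval 0.74 to 0.98, Fisher's exact test, two-sided, p = 0.0257, 0.0346 after Benjamini-Hochberg adjustment over 6 arm tests). For genes changed at least 2-fold it was 0.67 (95% interval 0.47 to 0.95, Fisher's exact test, p = 0.0230). Neighbouring genes are not independent. The unadjusted p stayed under 0.05 in 13 of 18 alternatives, with a highest p of 0.0897 without wild-type replicate 3, and it was 0.0718 without mutant replicate 1.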

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

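No result met a rule set for a closer look, since each genotype has 3 arrays, the design holds 1 contrast, and no control probe set was higher in the mutant at an adjusted p under 0.05. That rule counted rises only, and 3 GAPDH control probe sets were lower in the mutant at the same threshold (limma). The patterns here are those a biologist would most want to follow up. The bounds of the test on wild-type replicate 3 and the fits without wild-type replicates 1 and 2 were chosen after the medians per array had been seen, as was the demand that the marker medians keep their bound in every alternative, and the other tests in this part were planned. The bound on wild-type replicate 3 was also replaced after its value was seen: under a looser first bound the value, 24.0% of the difference in wild-type replicates 1 and 2, would have fitted carried tissue, and the open verdict turns on the replacement.

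The 1652 calls come from the real split of the 6 arrays. The highest of the other 9 splits gave 0 calls with limma (1133 probe sets at an unadjusted p under 0.05, against 3809 for the real split), and 1 of 10 splits, the real one, gave as many. With 10 splits the share cannot fall below 0.05, so the splits are too few for that test. The 3 other splits that part all 3 replicate pairs gave 0 calls and at most 592 probe sets at an unadjusted p under 0.05, and the 6 that part 1 pair gave 0 calls too. All 9 mix the genotypes, so a genotype difference widens their residual spread. Their 0 calls are therefore no measure of chance. Among the fits that leave out 1 array, the highest count was 1.60 times their median, reached with 1819 calls without wild-type replicate 3, so an effect of single arrays on the count stays open.

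The large changes, such as the rise of Rab40 and the loss of Elovl7, may in part reflect sequence differences between the stocks. Variants carried along with the homozygous chromosome 3 would raise the called share on 3R. The odds ratio there against X and chromosome 2 was 0.84 with an upper 95% bound of 0.97, so no excess was seen on that arm. This ratio covers all calls. For genes changed at least 2-fold, the odds ratio on 3R against X, 2L, 2R and 3L was 0.67 (95% interval 0.47 to 0.95). No excess was seen on 3R among these either, though that ratio counts 3L, which is part of chromosome 3, with the other arms. Both ratios take the arms compared with 3R as alike between the stocks, which was not tested, so they cannot weigh on variants spread over all arms. Variants under single probe sets would leave other probe sets of a gene behind, and for 16 genes with a called change of at least 2-fold and another probe set of similar brightness, that probe set showed a median share of 0.0517 of the change (95% bootstrap interval -0.0697 to 0.404). A low share decides nothing here, because each pair was chosen for a large change of its first probe set, a change in single transcript forms predicts the same, and 16 genes are few beside the 240 genes with such a change. An uneven RNA quality and the mutation itself stay open, since the 3-prime minus 5-prime difference of the mRNA controls moved by at most -0.040 between genotypes but the arrays are few, and that of the 18S ribosomal control was -1.01 ± 0.57 (SD, n = 3) in the mutant against -0.0096 ± 1.17 in wild type.

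The loss of Cp16, Cp18 and Cp19 may reflect regulation in follicle cells or a different mix of egg chamber stages. The planned bound against a stage mix was that chorion genes move in opposite directions beyond their errors. That was met, with 3 below 0 and Cp7Fc above 0 by over 2 SE, but the bound was wrong by design, because the list joins genes of different clusters, which are active at different stages, and a changed mix can move these apart. The median change of the 7 chorion genes was -0.11 (-0.057 without wild-type replicate 1, -0.064 without 3 and -0.21 without 2), and 3 of the 7 genes sit at the ceiling on all arrays and 5 in wild type, Cp16 and Cp19 among them. Stage mix and genotype cannot be told apart in whole ovaries for these genes.

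The lower basement membrane list may reflect muscle and sheath tissue carried in wild-type replicates 1 and 2. Muscle, the marker list that moved most, had a median change of -0.24, which met the planned bound of 0.25 against carried tissue. Its 95% bootstrap interval (-0.42 to -0.13) met the planned limit of 0.5. That interval resamples genes and not arrays, so it gives no measure of the spread between arrays. The median was -0.12 without wild-type replicate 2 and 0.095 without wild-type replicates 1 and 2, both outside the interval. The bound of 0.25 was too close to decide, since 6 of 19 alternatives passed it (-0.37 without wild-type replicate 3), so carried muscle stays open. The other 5 marker lists kept within it in all alternatives, but many of their members are dim and could hardly show a fall. For the basement membrane list, wild-type replicate 3 lay 0.13 above the mutant mean in the median, with 11 of 18 genes above it, against 0.56 for wild-type replicates 1 and 2, while the muscle markers lay at -0.09 for replicate 3 and 0.37 for replicates 1 and 2. That 1 array with muscle markers at the mutant level kept part of the difference decides nothing alone, so the carried tissue and the genotype cannot be told apart for this list.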

How the results depend on the processing

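Leaving out wild-type replicates 1 and 2 was added after the data were seen, and the remaining wild-type array was then assumed to vary like the mutant arrays. Quantile normalization, both centrings, the filter on dim probe sets, both treatments of genes with several probe sets, trend and robust eBayes, array weights, the replicate block and the pseudocount kept all counts of probe sets and of lists within 1.5 times. The scalings moved the median of all probe sets to at most -0.03. ry kept its direction and its call in all 17 alternatives. Of 86 named genes called, 63 were called in all 6 fits that leave out 1 array. Fewer samples give less power, but the count of calls rose to 1819 without wild-type replicate 3. The cause of the lost calls was not tested.

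With 1 array left out the count of calls ran from 1007 to 1819, that of higher probe sets from 533 to 857, that of lower from 474 to 962 and the number of lists past the test from 3 (without wild-type replicate 2) to 7. The odds ratio for 3R ran from 0.80 to 0.89 and missed the threshold without wild-type replicate 3 or mutant replicate 1. It was 0.88 after centring on the 75th percentile (Fisher's exact test, p = 0.0722), 0.88 with 1 probe set per gene (p = 0.0639) and 0.89 with averaged probe sets (p = 0.0743), and the cause was not tested. Without wild-type replicates 1 and 2 there were 1068 calls, 550 higher and 518 lower, of which 891 were among the 1652, and 0 lists passed camera (4 at an unadjusted p under 0.05), with a muscle median of 0.095 that turned in direction. Of 32 lists, 0 passed with an estimated correlation (1 at an unadjusted p under 0.05) and 1 with directional fry. That 1 list is Pax, shi and mirr, which the study chose on these samples. The estimated correlation was 0.40 for basement membrane, 0.48 for muscle, 0.29 for DNA replication and 0.36 for the cell cycle. For Pax, shi and mirr it was 0.04. A preset of 0.01 lies below each of these, and a lower correlation gives smaller camera p-values. With mixed fry, which asks for changes in either direction and compares with no other genes, 27 passed.

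The replicate block gave 1712 calls, 1500 of them among the 1652. It ended the calls of shi (adjusted p = 0.0512), Nrg (0.0594), papi (0.0634) and Obp99b (0.0510), added twe, stv and elav and added the integrin list, and it changed no other call of a named gene or list. Dim values limit the losses, since probe sets near the array floor of about 3 cannot fall further.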

Other observations

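The tests on chromosome 4 and the look at mutant replicate 3 were chosen after their results were seen.

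Genes of the small chromosome 4 were called more often than others. Of 65 genes there, 15 were called (23.1%), 8 higher and 7 lower, an odds ratio of 2.51 against all other arms (Fisher's exact test, two-sided, p = 0.0038, 0.0227 after adjustment over 6 arm tests). For genes changed at least 2-fold the odds ratio was 2.54 (95% interval 0.51 to 7.87, Fisher's exact test, p = 0.124). The zinc transporter gene Zip102B rose by 2.30 ± 0.15 (SE) and Rnf11, a RING finger gene, changed by -2.32 ± 0.16. dati changed by -1.10 ± 0.12, ci, the transcription factor of Hedgehog signalling, by -0.56 ± 0.10, and PlexB, a semaphorin receptor gene, by 0.49 ± 0.08 on its brightest probe set, while its other probe sets disagree at 3.15, -0.06 and -0.0090. A candidate explanation is that genes of chromosome 4 are brighter, but among genes of similar mean level the odds ratio was 2.86 (95% interval 1.40 to 5.60), which argues against brightness. A chromosome 4 that differs between the stocks stays open as an untested hypothesis, and no biological explanation was tested.

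Mutant replicate 3 stood nearest to wild type for many of the genes that were lower in the mutant. Of 121 genes lower at least 2-fold, mutant replicate 3 had the highest mutant value for 78, and for 6 of these it exceeded both other mutant arrays by over 1 on the log2 scale. These were CG15571, CG31926, Elovl7, CG12716, CG15570 and Cyp12d1-d, which lay 2.45, 2.32, 1.82, 1.49, 1.49 and 1.13 above the mean of the other mutant arrays. Of 106 genes higher at least 2-fold, mutant replicate 3 had the lowest mutant value for 35, and for 0 by over 1.

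Genes with several probe sets held opposite or unequal changes. For jim, a zinc finger gene, a probe set rose by 4.11 while another of similar brightness gave -0.42. For hts, an adducin gene, the pair gave -1.84 and 0.37, and for the transcription factor gene lola -3.35 and 0.44. In all, 12 genes had probe sets called in both directions. Among the control probe sets, 3 had an adjusted p under 0.05, all for GAPDH, at -0.48, -0.50 and -0.48, while another GAPDH control pair on the array gave 0.18 and 0.21.

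Of the 22 muscle markers, 14 have a mean above 7 in these ovaries and 0 stand in another list, and the brightest, Argk1 (mean 11.64), Mlp60A (10.74) and Mp20 (10.42), had log2 changes of -0.25, -0.18 and -0.42 and were not called.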
